A study of Gallus gallus with 8 samples.

How the data were processed

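Per the labels' protocols, total RNA was extracted from 32 chicken livers, the RNA of 4 birds was combined into each of 8 pools, and samples with an RNA integrity number above 7.5 went into poly(A)-selected libraries. The birds were housed at 24 °C on day 21 and at 18 °C from day 22 until the experiment ended on day 48, with high-energy feed. A label entry gives day 42, under a heading that does not say whether this is the age at sampling, so no age is assigned here. The submitters' processing notes name FastQC 0.10.1, Trimmomatic 0.10.1, Bowtie2 2.0.6, TopHat2 2.0.9, Cufflinks 0.10.1, Cuffdiff 0.10.1, HTSeq 0.6.1, DESeq2 1.22.1 and R 3.5.1, with no role or order. The genome build and annotation are not given in the sources used here.

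The deposited table holds values on a log2 scale, although it is named as counts. All 8 columns share 1 lowest value, 4.11, which stands for a count of 0, and the deposited log2 values follow the closed form of a variance-stabilizing transformation of counts divided by size factors. This was tested on the file: inverting that form gave whole multiples of 1 step in every column for 100% of values, within a tolerance of 0.01 of a read (largest deviation 0.0059). The steps gave the total reads and size factors of each pool, and these factors lay between 0.998 and 1.002 times the median-ratio factors of the recovered reads. Normalized reads in the text are recovered reads divided by these factors. The table holds no gene with fewer than 6 reads over the 8 pools. Reads are not molecules, and the depth of 26459951 to 33193179 reads per pool limits counting error only.

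The design fixed before the data were examined assumed raw counts and a count model. The values turned out to be on a log2 scale, so limma 3.58.1 (R 4.3.3, statmod 1.5.0) was used on the deposited values, with the variance trend and robust options, and with the samples, covariates and threshold of that design. Genes needed at least 10 reads per library of median size in 2 or more pools and 15 reads in all, which left 13766 of 14634. The ascites and sex effects came from 1 additive model of sex and status over all 8 pools. The effects within each sex and the interaction came from a model of 4 group means. P-values were adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes on this scale understate those of scarce genes.

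Measures of whole pools were compared by exact permutation over all assignments of 4 labels to 8 pools. Principal components used the 500 most variable genes. Where the labels do not say that the same replicate number marks a shared batch, the numbers were not used to pair pools. The fits were tested on simulated data with 200 changed genes in each of 5 runs. For the ascites effect they recovered 32.4% of 2-fold and 88.0% of 4-fold changes with 4.68% false calls. For the effect in females the shares were 12.2% and 69.6%, with 4.73% false calls, and for the interaction 1.22% and 21.5%, with 4.27% false calls. The simulation gave genes of similar abundance a common dispersion, the same in all pools, and held no pool that stood apart. These rates therefore need not hold for the real pools.

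Named genes were to be the 10 largest changes in each direction among genes that passed, had at least 1 CPM on average and changed the same way in both sexes, together with members of 47 gene lists and 10 preset genes. The files do not pair their IDs with names, and 0 IDs could be matched to the 25635 genes of the reference table (assembly GRCg7b), whose Ensembl column holds 0 filled cells. This says nothing about which of the genes that assembly contains. The named genes were therefore limited to the 2 largest in each direction. The gene lists and preset genes were not analysed here.

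Alternatives planned before the data were examined were other size factors (trimmed means of M values, upper quartile, total reads), no filter, a filter of 5 CPM in 2 pools, limma-voom with sample quality weights, non-robust variances, a replicate block, each pool left out in turn, other models, a test against a fold of 1.5 and fits within 1 sex. Limma-voom without weights on the recovered reads, log2 of normalized reads plus 1, and the joint omission of healthy female 2 and healthy male 1 were added after seeing the data.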

Results

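Liver messenger RNA was sequenced from meat-type chickens that had either developed ascites or stayed healthy while all of them were kept in the cold on an energy-rich diet. Ascites of meat-type birds is the build-up of fluid in the body cavity that accompanies pulmonary hypertension. RNA from 32 livers was combined into 8 pools of 4 birds, 2 pools for each of 4 groups: healthy females, healthy males, ascitic females and ascitic males. Every group met the cold, so the comparisons below are between disease states under cold, not between cold and warm housing. Ascites was not assigned to birds, so the ascites effect below names a difference, not a cause. The replicate is the pool, and the spread between birds inside a pool was not measured. The files identify genes by Ensembl ID and do not pair the IDs with names. Genes are therefore described here by direction, size and abundance, and only 4 are given by ID.

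The deposited table covered 14634 genes. Total reads per pool ranged from 26459951 in healthy female 1 to 33193179 in ascitic female 1, and the difference between the 4 healthy and 4 ascitic pools was within their spread (exact two-sided permutation test, p = 0.286). At these depths a gene with no read in healthy female 1 can have held up to 1.1e-05% of the reads of that pool, and such floors cover counting error only. The 2 pools of each group were not 1 library deposited more than once, since the chi-square per degree of freedom between them ran from 42.2 in ascitic females to 604 in healthy females.

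The first axis of variation separated the pools by disease status, and it also spread the healthy pools widely. The first principal component of the 500 most variable genes held 59.6% of their variance and was negative in all 4 healthy pools (from -44.0 to -4.39) and positive in all 4 ascitic pools (from 13.7 to 29.5). Within the ascitic birds, the pools of each sex lay close together, and their Spearman correlations across genes were 0.984 for the females and 0.974 for the males. Between the healthy pools of a sex they were 0.962 for the males and 0.900 for the females. The value of 0.900 was the lowest that healthy female 1 had with any pool, ascitic pools included. Healthy female 2 lay apart from every other pool. Its correlations with the other 7 pools were between 0.841 and 0.923, and 1441 genes were more than 1 log2 unit higher in it than in any other pool, against at most 27 genes in each of the other pools. Those genes held 45.0% of its reads, and 202 genes were more than 1 log2 unit lower in it than in any other pool. Scaled by total reads the balance turned, with 373 genes above and 1727 below all other pools.

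**Figure D1:**
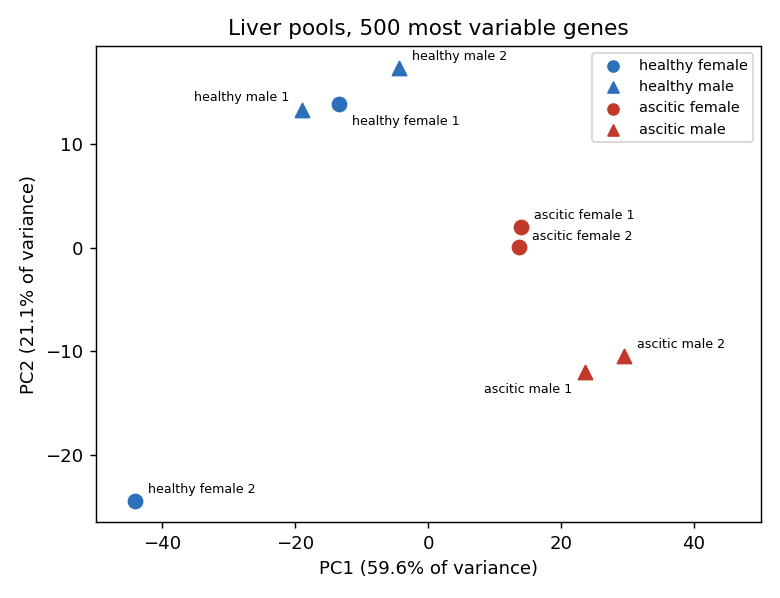
Principal components 1 and 2 (axis labels give the share of variance) of the 500 most variable genes, with 1 point per pool of 4 livers. All 4 healthy pools lie below 0 on the first component and all 4 ascitic pools above 0, and healthy female 2 lies at -44.0.

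The first comparison asked which liver transcripts differ between ascitic and healthy birds of both sexes. Of 13766 genes tested, 1384 (10.1%) passed an adjusted p of 0.05 in limma, 769 higher and 615 lower in ascitic birds. The median log2 fold change was 1.16 among the higher genes and -1.31 among the lower ones. Among these 1384 genes, estimates were over 2-fold for 534 higher and 475 lower genes, and over 4-fold for 63 and 76. All 4 ascitic pools lay above all 4 healthy pools for 717 of the 769 higher genes, and below them for 593 of the 615 lower genes. Passing the threshold itself favours large estimates and pools that do not overlap. Tested against a fold of 1.5 in limma, 121 genes passed. Over all tested genes the 4 and 4 pools did not overlap for 2934 (21.3%), where chance gives 2.86%.

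On the deposited scale the largest rise among genes open to naming was that of ENSGALG00000016785, from 159 ± 63.9 normalized reads in healthy pools to 6957 ± 5492 in ascitic pools (SD, n = 4 each). Its log2 fold change was 4.49 with a standard error of 0.67 (limma, adjusted p = 0.00646). Its level was 467.5 normalized reads in ascitic female 2 and 4338 or more in the other 3 ascitic pools, against at most 247 in any healthy pool. With healthy female 2 and healthy male 1 both left out, its log2 fold change was 4.23 and no longer passed (limma, adjusted p = 0.104).

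ENSGALG00000027345 was nearly silent in healthy liver and readily measured in ascitic liver. It went from 14.4 ± 17.7 to 534 ± 230 normalized reads (SD, n = 4 each), with a log2 fold change of 3.87 and a standard error of 0.46 on the deposited scale (limma, adjusted p = 0.00297). On scales that compress low levels less, its log2 fold change was 5.89 (log2 of normalized reads plus 1), 6.26 (limma-voom) and 6.95 (limma-voom with sample weights), against 4.75, 4.96 and 5.30 for ENSGALG00000016785, so the order of these genes turned. The highest healthy pool held 39.3 normalized reads of it, and the lowest ascitic pool held 206.

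The largest fall on the deposited scale was that of ENSGALG00000043779, an abundant liver transcript at 63273 ± 27862 normalized reads in healthy pools and 1906 ± 1224 in ascitic pools (SD, n = 4 each). Its log2 fold change was -5.17 with a standard error of 0.50 (limma, adjusted p = 0.00187), and the ratio of the means, healthy over ascitic, was 33.2. ENSGALG00000005739 fell from 24954 ± 11824 to 933 ± 550 normalized reads (SD, n = 4 each), with a log2 fold change of -4.70 and a standard error of 0.49 (limma, adjusted p = 0.00193). For both genes the lowest healthy pool exceeded the highest ascitic pool, by 36238 against 3305 and by 10370 against 1712 normalized reads.

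**Figure D2:**
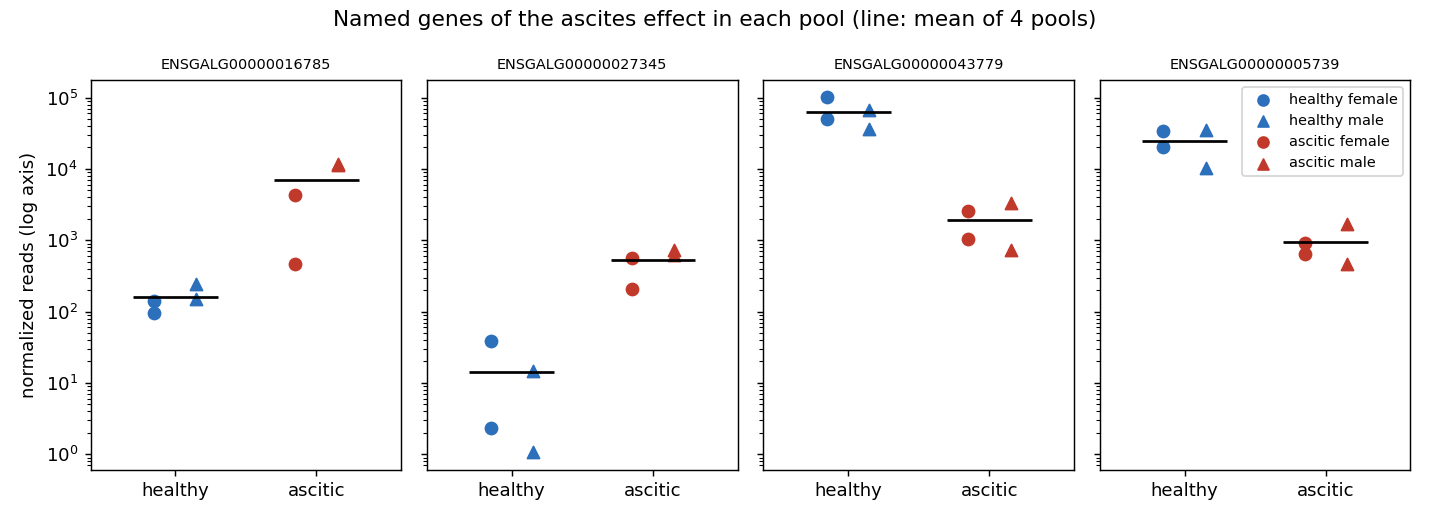
Normalized reads (log axis) of the 4 named genes in each pool, healthy in blue and ascitic in red, circles for females and triangles for males, with a line at the mean of 4 pools. The healthy and ascitic pools do not overlap for any of the 4 genes, and ENSGALG00000016785 is lowest among ascitic pools in ascitic female 2.

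Relative to the rest, abundant transcripts were shifted towards lower levels in ascitic birds. Among the 100 most abundant genes, 17 were lower and 5 higher in ascitic birds, so that lower genes were over-represented in this class (Fisher's exact test across genes, two-sided, odds ratio 4.47, p = 1.88e-06). Higher genes were not by the same Fisher's exact test (odds ratio 0.889, p = 1). Fisher's exact test here counts genes of the same 8 pools as independent, so its p of 1.88e-06 overstates the evidence. Over pools, the shift of the 1000 most abundant genes against the rest gave an exact two-sided permutation p of 0.0286, the smallest possible. Among the next 900 genes by abundance, 132 were lower and 27 higher. Among the 4000 genes after those the numbers were 217 and 176, and among the 8766 scarcer genes 249 and 561. Of the 769 higher genes 46 went from under 1 CPM on average in healthy pools to over 5 CPM in ascitic pools, and of the 615 lower genes 4 made the reverse change. CPM is scaled by total reads, which favours rises here. The median log2 fold change was -0.47 for the 1000 most abundant genes and 0.05 for the rest. Scaled by total reads these medians were 0.15 and 0.50, so the direction of the abundant class depended on the scaling.

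**Figure D3:**
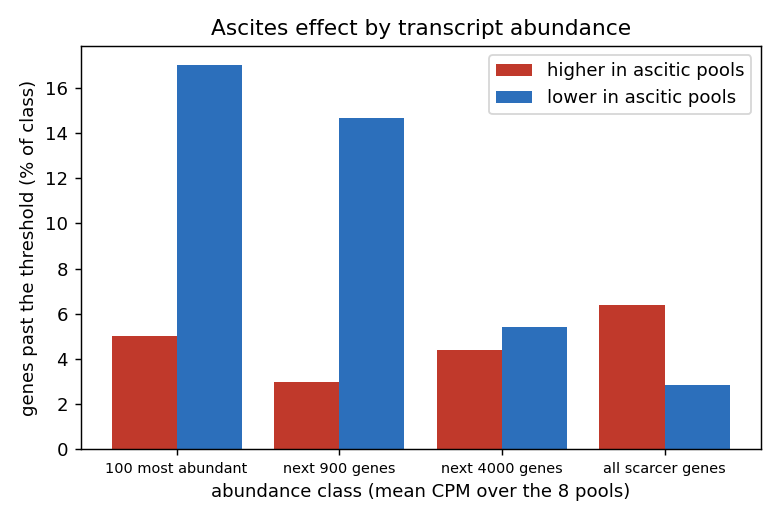
Share of genes past the threshold (percent of each class) that were higher (red) or lower (blue) in ascitic pools, by class of mean abundance over the 8 pools. Lower genes make up 17% of the 100 most abundant genes and 2.84% of the 8766 scarcest genes.

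None of 6 measures of whole pools passed after adjustment, but this could hardly have come out otherwise. With 4 against 4 pools, passing needed most of the 6 measures to reach the smallest possible exact permutation p, 0.0286. The size factor, the size factor divided by total reads and the number of genes read reached it, each without overlap. The size factor thus entered more than once, and the adjusted result says little about these measures. The share of reads in the 10 most abundant genes was 32.6% ± 4.67 in healthy and 29.7% ± 3.27 in ascitic pools (SD, n = 4 each; exact two-sided permutation p = 0.371), and that of the 50 most abundant 54.8% ± 4.55 and 49.5% ± 3.81 (exact permutation p = 0.143, adjusted p = 0.214). Genes with at least 1 read numbered 14197 ± 92.4 in healthy and 14410 ± 67.3 in ascitic pools (SD, n = 4 each; exact two-sided permutation test, p = 0.0286, adjusted over 6 measures p = 0.0571). The authors' size factor was 0.804 ± 0.217 in healthy and 1.32 ± 0.229 in ascitic pools, without overlap (SD, n = 4 each; exact permutation p = 0.0286, adjusted p = 0.0571), and 0.0286 is the smallest p that 4 against 4 pools can give. With scaling by total reads in place of those factors the median log2 fold change of all genes was 0.48, against 0.02 with them, and 2541 genes passed, 2293 higher and 248 lower, so the balance of 769 to 615 rests on the size factors. The number of genes was 2641 without healthy female 2, 362 without healthy male 1, 476 without ascitic female 1, 424 without ascitic female 2, 501 without ascitic male 1 and 377 without ascitic male 2.

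The second comparison asked how ascitic and healthy livers differed within each sex. In males 457 genes passed, 279 higher and 178 lower in ascitic birds, with median log2 fold changes of 1.94 and -2.07. In females 5 genes passed, 3 higher and 2 lower, with medians of 2.67 and -3.08. At an unadjusted p under 0.05 the numbers were 2508 in males and 2959 in females. Scaled by total reads, 450 genes were higher and 95 lower in males, and 191 higher and 20 lower in females. The genes that passed in males moved the same way in females for 430 of 457 (94.1%), with median female log2 fold changes of 1.09 for those higher and -1.06 for those lower in males.

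Across all tested genes the female and male log2 fold changes, which share no pool, had a Pearson correlation of 0.56 and a Spearman correlation of 0.54; genes are not independent replicates. The Pearson correlation was 0.41 without healthy male 1 and 0.63 without healthy female 2. With all pools the sign was the same for 69.6% of genes. At an unadjusted p under 0.05 in each sex, 599 genes were higher in both sexes, where independent lists give 154, and 468 were lower in both, where they give 114. Only 26 genes passed that limit in opposite directions. Both tests used the same estimate of spread for each gene, so the lists are not independent, and 154 and 114 understate the overlap by chance. A shared spread would raise the number of opposite pairs as well.

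**Figure D4:**
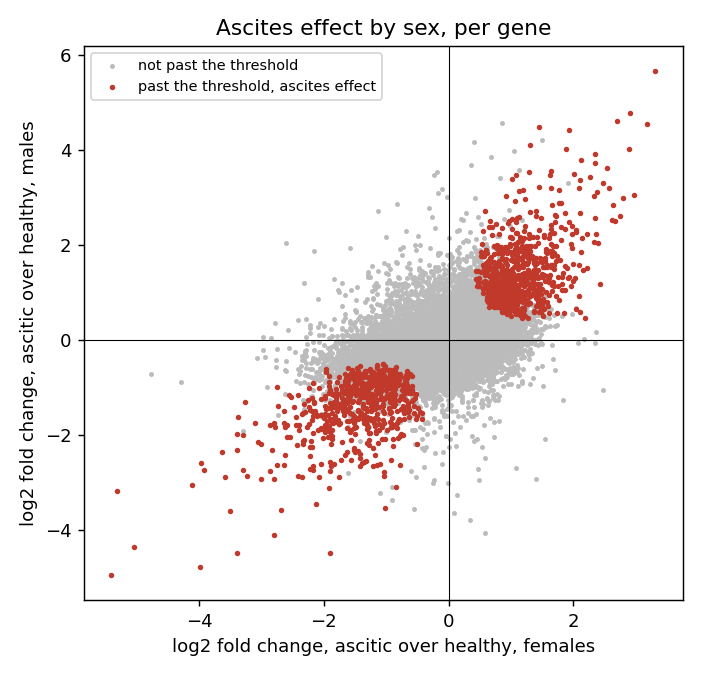
Log2 fold change of ascitic over healthy pools in females (horizontal) and males (vertical), 1 point per tested gene, with genes past the threshold of the ascites comparison in red. The correlation across all genes is 0.56, and the red genes were selected on the mean effect of both sexes, which favours equal signs.

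The difference between ascitic and healthy birds was then compared between the sexes gene by gene. The interaction test in limma passed 0 genes (835 at an unadjusted p under 0.05, smallest adjusted p = 0.249), and limma-voom passed 0 with and without sample weights, so the gap between 457 and 5 genes does not show that the sexes differed. The counts within a sex depended on single pools, also of the other sex, because all 4 groups shared 1 estimate of spread per gene. Leaving out a female pool did not change the male log2 fold changes (median over all genes 0.0059), only the spread they were tested against. A pool left alone in its group added nothing to that spread, as healthy female 2 without healthy female 1. Changes in the counts therefore partly reflect the shared spread. In males they were 1769 without healthy female 1, 1763 without healthy female 2, 0 without healthy male 1, 13 without healthy male 2, 154 without either ascitic female pool, 5 without ascitic male 1 and 0 without ascitic male 2. In females they were 5050 without healthy female 1, 207 without healthy female 2 and 0 without any one of the other 6 pools, and the interaction passed 2227 genes without healthy female 1.

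The third comparison was between males and females of both disease states. It passed 0 genes in limma (927 at an unadjusted p under 0.05, smallest adjusted p = 0.0988), 0 in limma-voom and 101 in limma-voom with sample weights. A group of 11 genes was nevertheless read in every female pool and nearly absent from 3 of the 4 male pools. Each had at least 50 normalized reads in all 4 female pools and at most 5 in healthy male 2, ascitic male 1 and ascitic male 2, where the highest value was 4.59. This group was chosen after the values were seen and without the pool labelled healthy male 1. Summed over the 11 genes, normalized reads were 14030 and 14499 in the healthy female pools, 6493 and 8969 in the ascitic female pools, and 3.17, 6.43 and 3.85 in those 3 male pools.

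The pool labelled healthy male 1 held 5585 normalized reads of the same 11 genes. Every one of them exceeded 5 normalized reads there, at a median of 35.7% of the healthy female mean (interquartile range 22.8% to 49.5%, lowest 14.1%, highest 81.5%). Without that pool 26 genes passed the sex comparison, all of them lower in males, and without healthy female 2 it passed 3. Values that rest on the healthy male group, among them the 457 genes called in males, include this pool.

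**Figure D5:**
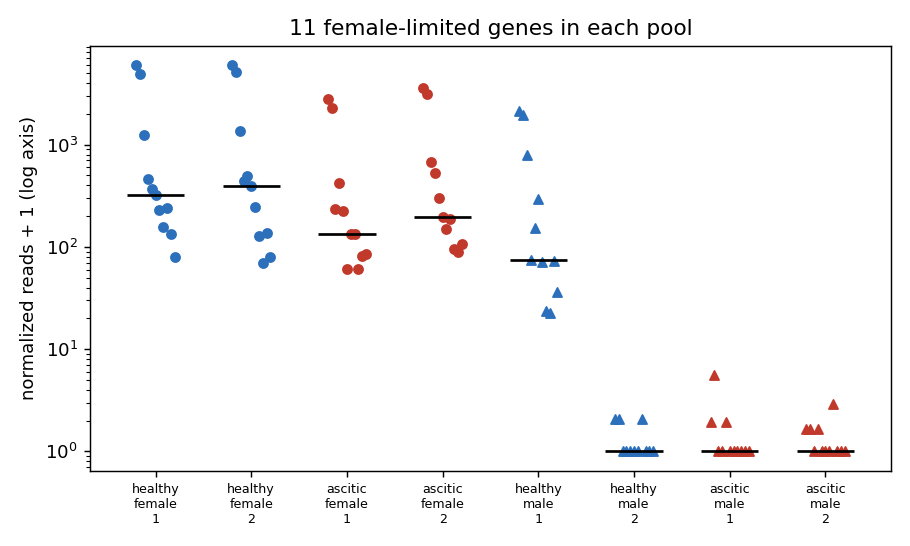
Normalized reads plus 1 (log axis) of the 11 female-limited genes in each pool, 1 point per gene and a line at the median, circles for pools labelled female and triangles for pools labelled male. The pool labelled healthy male 1 holds all 11 genes, while healthy male 2 and both ascitic male pools hold at most 4.59 normalized reads of any.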

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

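The tests for healthy female 2 were chosen after the pattern was seen, and only for its scaling was the bound written before the value. Each of 26 sets of 4 pools of 1 disease state was searched for a pool far from the other 3, by the gap to its neighbour over the whole range (Dixon test), and 4 sets held one. Chance gives about 1 in 20 for independent normal values. Some of these measures are counts of genes and several are related to each other, so that rate is no yardstick for the 4 sets.

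Healthy female 2 was far from the other healthy pools in 3 of them. It had 1441 genes over 1 log2 unit above and 202 genes over 1 log2 unit below all other pools, and its second principal component was -24.4. The tables argue against low total depth, since its 26821645 reads lay within the range of the other healthy pools, 26459951 to 30599393. Its size factor was 0.484, against 0.857 to 0.946 in the other healthy pools, and its 10 most abundant genes took 39.3% of its reads. Low depth for the remaining genes was not tested. The tables also argue against the size factors as the whole cause, since with scaling by total reads 2100 genes were still more than 1 log2 unit above or below all other pools, against at most 145 in any other pool. The direction did depend on that scaling, with 373 genes above and 1727 below. RNA quality and a difference between the birds pooled stay open, and no biological explanation was tested.

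The share of reads in the 10 most abundant genes was 34.6% in ascitic male 1, far from the other 3 ascitic pools, of which the highest held 28.3%.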

How the results depend on the processing

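The joint omission of 2 pools, limma-voom without weights and log2 of normalized reads plus 1 were chosen after seeing the data. The 1384 genes of the ascites effect became 2541 with total reads, 831 with the replicate block and 121 against a fold of 1.5, and the cause was not tested except that the last asks for a larger change. Of 22 alternatives, 13 stayed within 1.5 times the count. The 5 genes in females became 30 with trimmed means of M values, 32 with upper quartile factors, 211 with total reads, 34 with the 5 CPM filter, 30 with log2 of normalized reads plus 1, 0 with limma-voom, 0 with female pools only, 1 with the replicate block and 669 without both pools. The 457 genes in males became 991 with sample weights, 1079 with male pools only, 198 with the replicate block and 1373 without both pools. The sex effect rose from 0 to 101 genes with sample weights and 103 without both pools, and the interaction from 0 to 6 without both pools; the cause was not tested.

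With 1 pool left out, where the lone pool left in a group is assumed to vary like the other groups, counts ran from 362 (healthy male 1) to 2641 (healthy female 2) for the ascites effect, from 0 to 26 for sex, from 0 to 5050 in females, from 0 to 1769 in males and from 0 to 2227 for the interaction. The genes of the ascites effect shared with the 1384 were 358 of the 362 and 1378 of the 2641. The replicate numbers do not pair pools by any label, and deviations of same-numbered pools correlated from -0.42 to 0.32 between groups. The named genes kept their direction in all 22 alternatives each, and all but ENSGALG00000016785 without both pools (adjusted p = 0.104, range over its alternatives 0.000513 to 0.104) stayed past the threshold. Because the named genes were chosen as the largest changes in these same pools, their kept direction was nearly fixed by that choice and is no independent support. The correlation between the sexes ran from 0.41 without healthy male 1 to 0.63 without healthy female 2. The planned DESeq2 test, the autosome-only sex effect and the gene list tests were not run. The log2 fold change of ENSGALG00000027345 was 5.89 with log2 of normalized reads plus 1, 6.26 with limma-voom and 6.95 with sample weights. How depth limits the calls was not tested apart from pool number and spread.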

Other observations

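The tests in this part were chosen after the patterns were seen; only for the abundance pattern without healthy female 2 and with total reads were the bounds written before the values.

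The division into ascitic and healthy pools gave 1384 genes, and it was the only 1 of the 34 splits of the 8 pools that could be fitted with sex as covariate to give as many; the highest other split gave 0. Over these 34 splits the share that gave as many was under 0.05. The splits not balanced for sex overlap with the sex covariate, however, which lowers the number of genes they can call. Of the 18 among them that are balanced for sex, again only the real one gave as many. These 18 are too few for a share under 0.05, so they cannot exclude chance at that share. For the sex effect, a real count of 0 makes all 34 splits give as many whatever the data (the highest other gave 0), so the splits say nothing about chance there.

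The median log2 fold change of the 1000 most abundant genes minus that of the rest was -0.64 in females and -0.44 in males, and -0.51 over all 8 pools (exact two-sided permutation p = 0.0286, the smallest possible), while within a sex the 4 pools allow no exact p under 0.333, the value in both sexes. It was -0.46 without healthy female 2, where the real split was the most extreme of 35, which argues against that pool as the whole cause. Without healthy female 2 and healthy male 1 the difference was -0.45. The real split was then the most extreme of 15, so the exact permutation p of 0.0667 was the smallest possible. With total reads in place of the size factors the difference over all 8 pools was -0.34. On plain log2 reads of the 13016 genes read in every pool, where size factors cancel between the classes, it was -0.53 (exact two-sided permutation p = 0.0286), which argues against the size factors as the whole cause. The shares of reads in the 10 and 50 most abundant genes did not pass a test (exact permutation p = 0.371 and p = 0.143). Ascites itself, RNA quality and cell makeup stay open, untested.

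In birds only females carry the W chromosome, and whether the 11 female-limited genes lie on it is not known here. All 11 exceeded the level of the other male pools in the pool labelled healthy male 1, as RNA of female birds in this pool would give. All 11 also lay below both healthy female pools, but so did 9 of the 11 in ascitic female 1. In healthy male 1, 9 of the 11 lay below all 4 female pools, and 2 of the 11 exceeded both ascitic female pools. The ascitic pools differ from it in disease state, and 2 healthy female pools measure little of the spread between such pools. A pool of females under a wrong label was therefore not told apart from a mixed pool. Reads carried over from a single female library would keep 1 ratio over genes, but the ratio of the highest to the lowest share was 4.46 against the closest female library, with separate 95% intervals. One female among the 4 birds would give about 25% of the healthy female mean with equal livers. The observed median was 35.7%, and it was 36.8% with trimmed means of M values, 39.5% with upper quartile factors and 44.5% with total reads. Ascitic female pools also summed to less than the healthy ones, 6493 and 8969 against 14030 and 14499 normalized reads, with 5585 in healthy male 1. The median share therefore does not measure a number of birds, which stays open. Female RNA that entered before sequencing is a candidate explanation. Genes higher in males did not help to decide. At the median, healthy male 1 lay 40.1% of the way towards the females and the other male pools from 24.9% to 54.5%. Each male pool had its own set of 10 to 16 genes, in which the remaining male pools all exceeded the females. These shares are therefore not on 1 scale. For the pools other than healthy male 1, the choice itself required healthy male 1 to exceed the females.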
